A study of Mus musculus with 38 samples.

How the data were processed

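Messenger RNA levels of mouse CD8 T cell clones were measured on 38 Affymetrix arrays, 1 array per RNA sample. Per the labels, 100 ng of total RNA extracted with QIAGEN RNeasy was labelled with the WT Plus kit. The deposited values are log2 probe set summaries; Partek and RMA (robust multi-array averaging) are named in the submitters' processing notes, without version, order or settings. The log2 scale was checked from the values themselves, which ran from 2.14 to 14.76 with none missing. The level of summarization and whether all arrays were normalized together are not given in the sources used here. Arrays carry no read depth, so the number of arrays per group limits the precision.

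The table held 35556 rows. The platform annotation names a gene for 23410 of them, which were tested; 21789 of these carry 1 gene symbol and 1621 carry several. The other 12146 rows have no gene name in that annotation and enter only where stated. By their gene numbers, 21698 probe sets matched the mouse GRCm38.p6 gene table, which served for names and chromosomes only. The tested probe sets stand for 19938 distinct genes. Where several probe sets name 1 gene, the one with the highest mean over all arrays stands for it.

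Groups were taken from the labels: 5 clones in 2 states make 10 groups. Of these, 8 held 4 arrays, and dormant sAg1 and dormant sAg3 held 3 each. Each probe set was fitted with limma (version 3.58.1, R 4.3.3) with 1 mean per group, a spread shared by all groups and moderated variances with a mean trend. Each comparison is a contrast of clone means in which every clone has equal weight. A probe set was called at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 difference of at least 1, with a condition on the separate clones. For activation the direction had to be the same in all 5 clones; for phenotype comparisons the clone means of both sides, and for the difference in activation the activation effects of both sides, had to lie apart. Chance alone gives an equal direction in all clones in 6.25% of cases, a separation of 2 clones from 2 in 33.3%, and of 2 from 1 in 66.7%. Errors of differences are standard errors of the contrast (SE); errors of group means are standard deviations over arrays (SD). All tests were two-sided.

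The labels do not say whether arrays of 1 group came from separate cultures, so the p-values measure the spread between these arrays, which may be technical, and hold for these clones. The replicate numbers in the sample titles do not state a pairing. Across 18 pairs of dormant and activated arrays with the same clone and number, the correlation of their deviations from the group means ran from -0.236 to 0.268, and 7 exceeded 0.1. In 8uvmo-2 all 4 pairs exceeded 0.1, and a fit with the replicate number as a block was among the alternatives.

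Gene lists (29 lists, 642 symbols, 581 measured) cover T cell cytokine programs, receptors, metabolism, stress responses and markers of other lineages. They were tested with camera, a competitive test of a list against all other probe sets, at a preset correlation between genes of 0.01, with adjustment over the 29 lists of each comparison. The test was repeated with the correlation estimated per list, and both adjusted p-values are given where the second ends the call. Members of a list were counted as higher or lower at an adjusted p under 0.05 over all probe sets, without a minimum on the difference.

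The comparisons, the gene lists, the tests, the alternatives and the rule for named genes were set before the data were examined. The rule named 15 key genes of cytokines, regulators, coreceptors and cytotoxicity in every comparison, the 8 called genes with the largest difference per direction, and up to 4 called members per list. The largest differences were taken among probe sets with 1 symbol, leaving out predicted loci and the 25 probe sets of T cell receptor and immunoglobulin segments. Genes outside the rule are marked as chosen after their values were seen.

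Alternatives covered the fold minimum (none, or limma's treat test against a log2 difference of 1), a filter on dim probe sets and centring of each array on its median. They also covered quantile normalization, a variance model without trend, array weights and fits on the compared arrays alone. Further ones were 1 probe set per symbol, the replicate block, each array left out in turn and no condition on the clones. The unit of replication was changed to the clone, either as clone means or as a random block. Tests with each clone left out were planned for the gene lists. Chosen after seeing the data were all rows of the file, counts with each clone left out, a call in every pair of clones, and gene lists after quantile normalization. The procedure was tested on simulated data with changes of 1.5, 2 and 3 log2 units in 200 genes each: between 99.5% and 100% were recovered, with at most 1 false call per run. In the simulation the list test called the 1 list that had been shifted and no other. The simulated clones did not differ beyond these changes, and genes varied independently. False calls from differences between clones of 1 phenotype, or from correlated genes, were therefore not covered.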

Results

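Gene expression was measured in 5 mouse CD8 T cell clones, each in a dormant state and after 14 h on immobilised anti-CD3 antibody (145-2c11, 0.5 ug/ml). Clones sAg1 and sAg3 are labelled as IL13+ (called CD8γ13 in the series design), 8uvmo-2 and 8uvmo-3 as IL13-negative, and CD8bm1 as an alloreactive CD8 clone. Every group held 4 arrays except dormant sAg1 and dormant sAg3 with 3 each, which gave 18 dormant and 20 activated arrays. Arrays of 1 group correlated at 0.9858 to 0.9981 across probe sets. The array medians were 6.58 to 6.70 in the dormant state and 7.01 to 7.09 after activation. Values below 7, close to the median of all values (6.91), were treated as near background, though no background was measured. Where a clone of the lower side was below 7, a fold is given as a lower bound. The log2 difference of such a gene is a lower bound too. Neither is a bound where a clone of the higher side was also below 7, as for dormant Il13, Mest and Klra5. Such mean differences are given as measured. Il4 in every group and Il2 in every dormant group lay below 7, so their differences there say little. After activation Ifng (13.59 to 14.17), Gzmb (13.90 to 14.08) and, in 3 clones, Ccl3 (14.18 to 14.25) lay near the array maxima of 14.31 to 14.46, where differences can be compressed. Dormant 8uvmo-2 fell into 2 sets of arrays, replicates 1 and 3 (r = 0.9974) and replicates 2 and 4 (r = 0.9973), with 0.9858 to 0.9894 across the sets. The first principal component held 38.3% of the variance and parted the states, and the next 2 components (20.6% and 12.5%) parted clones.

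Chemokine transcripts were among the largest measured increases after 14 h on anti-CD3, in all 5 clones. Relative to the array medians, Ccl3, which attracts macrophages and T cells, rose by at least 5.97 ± 0.099 (log2 difference, SE), and Xcl1, a ligand for receptors of cross-presenting dendritic cells, by at least 5.62 ± 0.072. Ccl1, the ligand of Ccr8, rose by at least 5.45 ± 0.052 and Ccl4 by at least 4.42 ± 0.071. Dormant Xcl1 and Ccl1 lay below 7 in all 5 clones, and Ccl3 and Ccl4 in 3 each. Ifng, the signature type 1 cytokine, rose by at least 2.60 ± 0.038, since its activated values were near the array maxima, as were those of Ccl3. Il3, a haematopoietic growth factor, rose by 3.78 ± 0.088 on average, but by 0.10 in CD8bm1, where it stayed below 7 (5.03). Among decreases, the interferon-inducible Ifi206 fell by 3.79 (± 0.08), the lectin receptor gene Klrb1f by 3.48 (± 0.15) and the chemokine receptor gene Ccr2 by 2.93 (± 0.11). Activated arrays lay higher as a whole, with a median shift of 0.352 over all probe sets, so all values of this comparison are differences relative to the array medians, and the calls come from the test on the deposited values. Probe sets with a mean below 7 carried the shift (0.515), while those above 9 differed by -0.0452, so centring lowers bright genes as well. Those with a mean of 5 to 6 shifted by a median of 0.57, more than centring removes. Dim genes thus keep a small rise after centring.

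Of the remaining largest increases, Rgs16, a regulator of G protein signalling, rose by 4.68 ± 0.064, Akr1c18 by 4.28 ± 0.13, the scavenger receptor gene Olr1 by 3.98 ± 0.064 (0.52 in CD8bm1) and Inhba, which encodes an activin subunit, by 3.79 ± 0.10. Activated Olr1 stayed below 7 in sAg3 (5.85) and CD8bm1 (5.1), and activated Akr1c18 in sAg3 (5.39). Samhd1, a dNTP hydrolase, fell by 3.07, Ifi209 fell by 2.94, Ly6a2 fell by 2.94, Abcg3 fell by 2.89 and Selenop, a selenium carrier, fell by 2.85. Among the key genes, Il10 rose by 2.38 ± 0.091, Il2 by 1.73 ± 0.094, Tnf by 1.41 ± 0.055, Il13 by 1.24 ± 0.092 and Il5 by 1.18 ± 0.094. These averages hold clones that stayed below 7. Activated Il5 was at 5.46 in 8uvmo-2, 5.45 in 8uvmo-3 and 5.22 in CD8bm1, so its rise came from sAg1 and sAg3. Activated Il2 was at 6.34 in sAg3 and 5.37 in CD8bm1, and activated Il10 at 5.5 in 8uvmo-3. The call of Il13 and Tnf was lost after centring, since the centred difference of Il13 was 0.00 in CD8bm1 and that of Tnf was -0.01 in sAg3. On the deposited values Tnf went from 10.67 to 11.07 in sAg3, a level at which centring lowers genes. Prf1, which encodes perforin, was 0.69 higher relative to the array medians and also lost its call. Key genes that missed the minimum difference were Gzmb (0.48), Il4 (0.46), Cd8a (0.30), Cd4 (-0.05), Eomes (-0.12), Tbx21 (-0.14), Cd8b1 (-0.14) and Gata3 (-0.58). On the deposited values Cd4, Eomes, Tbx21 and Cd8b1 were higher after activation, by 0.35, 0.29, 0.26 and 0.26. The deposited differences of Prf1, Gzmb, Il4, Cd8a and Gata3 were 1.09, 0.88, 0.86, 0.70 and -0.18.

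For gene lists in activation, counts are given on the deposited values and then after centring, and the adjusted p-values come from the deposited values. Genes induced through the T cell receptor rose together: of 37 measured, 35 were higher and 1 lower (36 and 1 adjusted over the list alone), and 31 and 2 after centring. Examples are the immediate early genes Nr4a3 (3.61 ± 0.06), Egr2 (3.52 ± 0.05), Nr4a1 (3.04 ± 0.061) and Egr1 (2.80 ± 0.053). The list passed at an adjusted p = 0.000161 (adjusted p = 0.0728 with an estimated correlation). Of 20 chemokine ligands, 20 were higher and 0 lower (20 and 0 adjusted over the list alone; adjusted p = 0.00219, adjusted p = 0.179 with an estimated correlation), and 15 and 2 after centring. Of 33 interleukins and growth factors, 30 were higher and 2 lower (30 and 2 adjusted over the list alone; adjusted p = 0.00245, adjusted p = 0.0877 with an estimated correlation), and 23 and 4 after centring. Ribosome biogenesis genes were higher in 40 of 41 and lower in 0 (40 and 0 adjusted over the list alone), and in 33 and 4 after centring, with the rRNA processing genes Rrp9 at 1.38, Nop16 at 1.18 and Nop2 at 1.02 (adjusted p = 0.000362, adjusted p = 0.527 with an estimated correlation). Within the cytotoxic effector list, whose balance did not pass (adjusted p = 0.621), the granzyme B inhibitor Serpinb9 rose by 3.37 and Serpinb6b by 3.05, while the cathepsin gene Ctsw fell by 1.86.

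Chemokine and homing receptors fell on balance, with 11 of 28 higher and 15 lower (11 and 15 adjusted over the list alone; adjusted p = 0.00124, adjusted p = 0.0673 with an estimated correlation), and 8 and 17 after centring. The centred list did not pass (adjusted p = 0.0877; 0.00647 to 0.0877 over its alternatives). Cxcr4, the bone marrow homing receptor, fell by 2.83, Cxcr3, the receptor for interferon-induced chemokines, by 2.16 and Selplg, the P-selectin ligand, by 1.72. Genes of resting and memory T cells were higher in 10 of 26 and lower in 15 (10 and 15 adjusted over the list alone; adjusted p = 0.000716, adjusted p = 0.148 with an estimated correlation), and in 6 and 20 after centring, with Rasgrp2 at -2.05, Pik3ip1 at -1.82 and the survival gene Bcl2 at -1.71. Of 33 interferon-stimulated genes, 16 were higher and 14 lower (16 and 14 adjusted over the list alone), and 7 and 21 after centring. This list passed as lower than other genes (adjusted p = 0.00865, adjusted p = 0.274 with an estimated correlation) although its median was 0.04 (mean -0.09), and did not pass after centring (adjusted p = 0.0816; 0.00961 to 0.274 over its alternatives). Hypoxia genes were lower in 11 of 19 and higher in 3 (11 and 3 adjusted over the list alone; adjusted p = 0.000161, adjusted p = 0.425 with an estimated correlation), and in 17 and 1 after centring. Cell cycle genes were lower in 25 of 47 and higher in 7 (24 and 6 adjusted over the list alone; adjusted p = 4.72e-06, adjusted p = 0.527 with an estimated correlation), and in 38 and 0 after centring. Their median change set against all probe sets was -1.51 in 8uvmo-2, -1.51 in CD8bm1, -0.77 in 8uvmo-3 and -0.58 in sAg3, but 0.63 in sAg1. In 8uvmo-2 it came mostly from dormant replicates 1 and 3, with list medians of 10.52 and 10.51. Dormant replicates 2 and 4 were at 8.41 and 8.04, against 7.67 to 8.58 on the activated arrays. In sAg3 the list medians of single arrays overlapped, at 7.92 to 8.77 dormant and 7.76 to 8.3 activated. Markers of other lineages moved with activation as well: 17 of 17 stromal and epithelial markers were higher on the deposited values (adjusted p = 0.0317, adjusted p = 0.425 with an estimated correlation) and 14 of 17 after centring. Centring leaves dim members of any list part of the shift, so a centred count of dim genes does not by itself show regulation.

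Of the 29 lists, 13 passed at the preset correlation and 0 with the estimated one. In all, 1450 of 23410 probe sets were called, 1067 higher and 383 lower after activation. The split between higher and lower depended on the scaling: it was 248 and 1301 after centring and 430 and 620 after quantile normalization, and 597 probe sets (223 higher, 374 lower) were called in the same direction under all 3. Within single clones, 2778 probe sets were called in 8uvmo-2, 2537 in sAg1, 2355 in 8uvmo-3, 1697 in CD8bm1 and 1174 in sAg3; whether these counts differ was not tested.

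**Figure D1:**
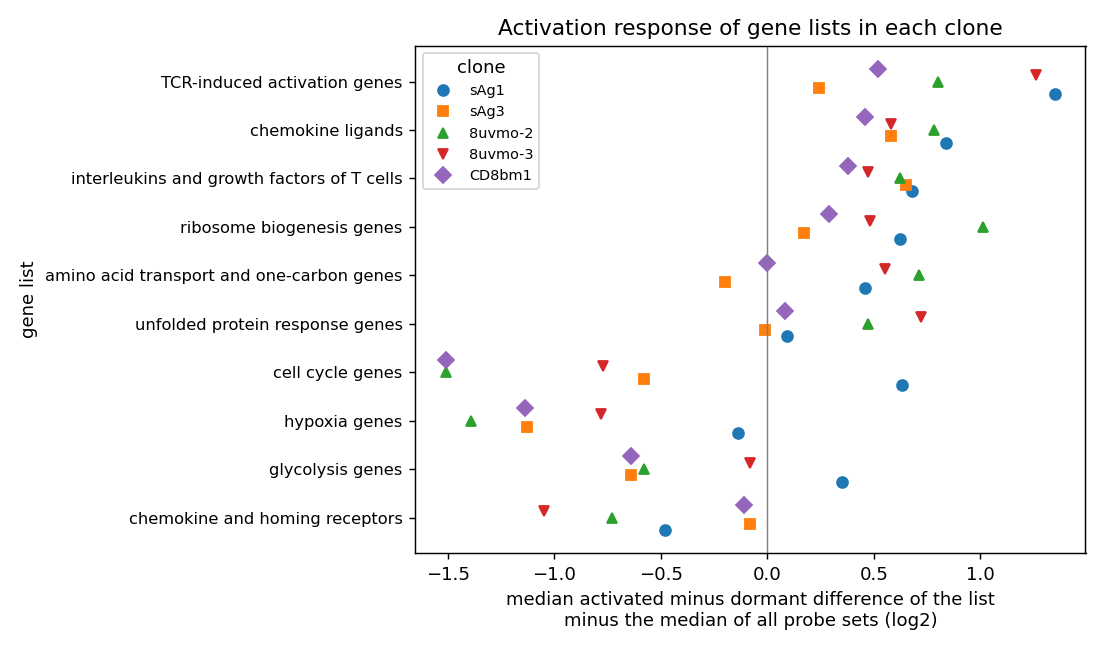
Activation response of gene lists in each clone: the median log2 difference (activated minus dormant) of a list's members, less that of all probe sets. The median of the T cell receptor-induced genes ran from 0.24 in sAg3 to 1.35 in sAg1.

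The IL13+ clones were next set against the IL13-negative clones in the dormant state, which asks what marks the phenotype without stimulation. Itga1 (probe set 10412298, chromosome 13), which encodes the collagen-binding integrin CD49a, was at least 125-fold higher in the IL13+ clones (log2 difference 6.96 ± 0.10, n = 6 and 8 arrays), with 12.24 ± 0.10 in sAg1 and 12.50 ± 0.04 in sAg3 (SD) against 5.67 and 5.15. Ccr8 (probe set 10590242, chromosome 9), a chemokine receptor of type 2 T cells, was at least 8.90-fold higher (3.15 ± 0.096). S1pr1 (probe set 10501586, chromosome 3), the receptor that lets T cells leave lymphoid tissue, was at least 18.6-fold lower (-4.21 ± 0.13). Il13 (probe set 10385837, chromosome 11) was 4.39-fold higher on average (2.14 ± 0.15), which is no lower bound. This mean came from sAg3 at 10.29, since dormant sAg1 lay at 6.24 beside 6.22 in 8uvmo-2. Il5 stood at 10.88 in sAg3 and at 4.56 in sAg1, so its mean difference of 3.14 was not called.

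Other large increases in the IL13+ clones were Lncenc1 (4.78 ± 0.11), Tmem273 (4.63 ± 0.11), the casein gene Csn1s1 (3.94 ± 0.16), the clock gene Arntl (3.68 ± 0.057), the adhesion molecule gene Pecam1 (3.43 ± 0.21), the imprinted gene Mest (3.40 ± 0.06) and Bcar3 (3.26 ± 0.093). Csn1s1, Pecam1 and Mest were driven by sAg3, at 12.01, 11.79 and 11.64 against 5.50, 6.52 and 4.94 in sAg1, and Csn1s1 (12.97), Itga1 (11.93), Lncenc1 (11.34) and Bcar3 (9.08) were also high in CD8bm1. Large decreases were Ly6e (-5.18 ± 0.12), Ccdc38 (-4.65 ± 0.11), Anxa8 (-4.54 ± 0.14), Rny1 (-4.43 ± 0.30), the NK receptor gene Klra5 (-4.43 ± 0.16), Lgi1 (-4.36 ± 0.13), Lxn (-4.33 ± 0.095) and the glycolytic Aldoc (-4.23 ± 0.24). Klra5 was at 12.06 in 8uvmo-3 and at 3.58 in 8uvmo-2, and Lgi1 at 10.23 and 5.87. Dormant CD8bm1 was low as well in Ly6e (5.94), Ccdc38 (4.76), Anxa8 (6.21) and Lgi1 (3.76). It was high in Rny1 (9.99), Klra5 (10.93), Lxn (10.28) and Aldoc (12.33). Among the key genes, Cd4 was 2.35 ± 0.12 higher and Il10 was 2.15 ± 0.15 higher, both more in sAg3. Cd4 was at 10.45 in sAg3 and 7.85 in sAg1, where 1 array (7.39) equalled the highest of 8uvmo-2. Il10 was at 7.93 in sAg3 and below 7 in sAg1 (6.77). Eomes (2.00), Gata3 (0.90), Cd8b1 (0.64) and Tbx21 (-0.52) passed the adjusted p but not the other conditions, as did Prf1 (0.37), Cd8a (-0.25) and Gzmb (0.17). Il4 (0.15), Tnf (0.11), Il2 (0.10) and Ifng (-0.13) did not differ past the test.

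Of 27 genes of type 2 cytokines and their regulators, 12 were higher and 2 lower in the IL13+ clones (13 and 2 adjusted over the list alone; adjusted p = 2.83e-05, and adjusted p = 0.0186 with an estimated correlation). Besides Ccr8, the phosphatase gene Dusp4 (3.07, with 10.75 in sAg3 against 6.67 in sAg1) and Hpgds (2.78), the prostaglandin D2 synthase of haematopoietic cells, were higher. Hpgds was at 9.44 in sAg3 beside 8.65 in 8uvmo-2 and 5.7 in 8uvmo-3. Cell cycle genes were lower, with 38 of 47 lower and 1 higher (38 and 1 adjusted over the list alone; adjusted p = 2.22e-07, adjusted p = 0.685 with an estimated correlation). Cyclin A2 (Ccna2) was at 6.65 ± 0.70 in sAg1 and 9.02 ± 0.70 in sAg3 against 10.88 ± 1.48 and 9.62 ± 0.44. Both sets of dormant 8uvmo-2 arrays differed in these genes: the median of the list was 10.52 and 10.51 in replicates 1 and 3 but 8.41 and 8.04 in replicates 2 and 4, beside 7.92 to 8.77 in sAg3, 7.11 to 7.59 in sAg1 and 8.26 to 9.23 in 8uvmo-3. Without 8uvmo-2, 18 were lower and 1 higher (adjusted p = 0.00145; 3.39e-09 to 0.685 over its alternatives). Genes of the unfolded protein response were higher in 16 of 21 and lower in 0 (17 and 0 adjusted over the list alone; adjusted p = 2.98e-08, adjusted p = 0.114 with an estimated correlation), with Sel1l, part of the degradation machinery of the endoplasmic reticulum, at 1.15. Amino acid transport and one-carbon genes were higher in 16 of 26 and lower in 3 (18 and 3 adjusted over the list alone; adjusted p = 2.83e-05, adjusted p = 0.277 with an estimated correlation), with the transporter genes Slc1a4 at 1.87 and Slc7a5 at 1.55 and the mitochondrial folate enzyme gene Mthfd2 at 1.47.

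Homing receptors were lower in 14 of 28 and higher in 4 (14 and 6 adjusted over the list alone; adjusted p = 0.00667, adjusted p = 0.0963 with an estimated correlation). The integrin gene Itga4 (-3.35) and the gut homing receptor gene Gpr15 (-3.27) are examples. NK receptors were lower in 12 of 21 and higher in 5 (13 and 5 adjusted over the list alone; adjusted p = 0.000819, adjusted p = 0.114 with an estimated correlation), with Klrb1f at -1.51. Genes of type 1 cytokines and their regulators were lower in 12 of 23 and higher in 5 (13 and 6 adjusted over the list alone; adjusted p = 0.012, adjusted p = 0.32 with an estimated correlation), with Ccl5 at -2.18 and Il12rb2, part of the IL-12 receptor, at -1.40 but lymphotoxin alpha (Lta) at 1.11. Without sAg3 this list turned its direction (adjusted p = 0.921; 0.000461 to 0.921 over its alternatives). Markers of macrophages and dendritic cells were higher in 10 of 26 and lower in 2 (13 and 2 adjusted over the list alone), which did not pass (adjusted p = 0.055).

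Of the 29 lists, 8 passed here and 1 of them (type 2) also with the estimated correlation. In this comparison 784 probe sets were called, 239 higher and 545 lower in the IL13+ clones. Arrays of 1 clone are not separate clones: with clone means as replicates, 36 remained (2 higher, 34 lower), with Itga1 and S1pr1 among them but not Il13 or Ccr8. The count was 1540 without sAg1 and 1231 without 8uvmo-2, and 212 probe sets (45 higher, 167 lower) passed in every pair of clones across the sides.

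**Figure D2:**
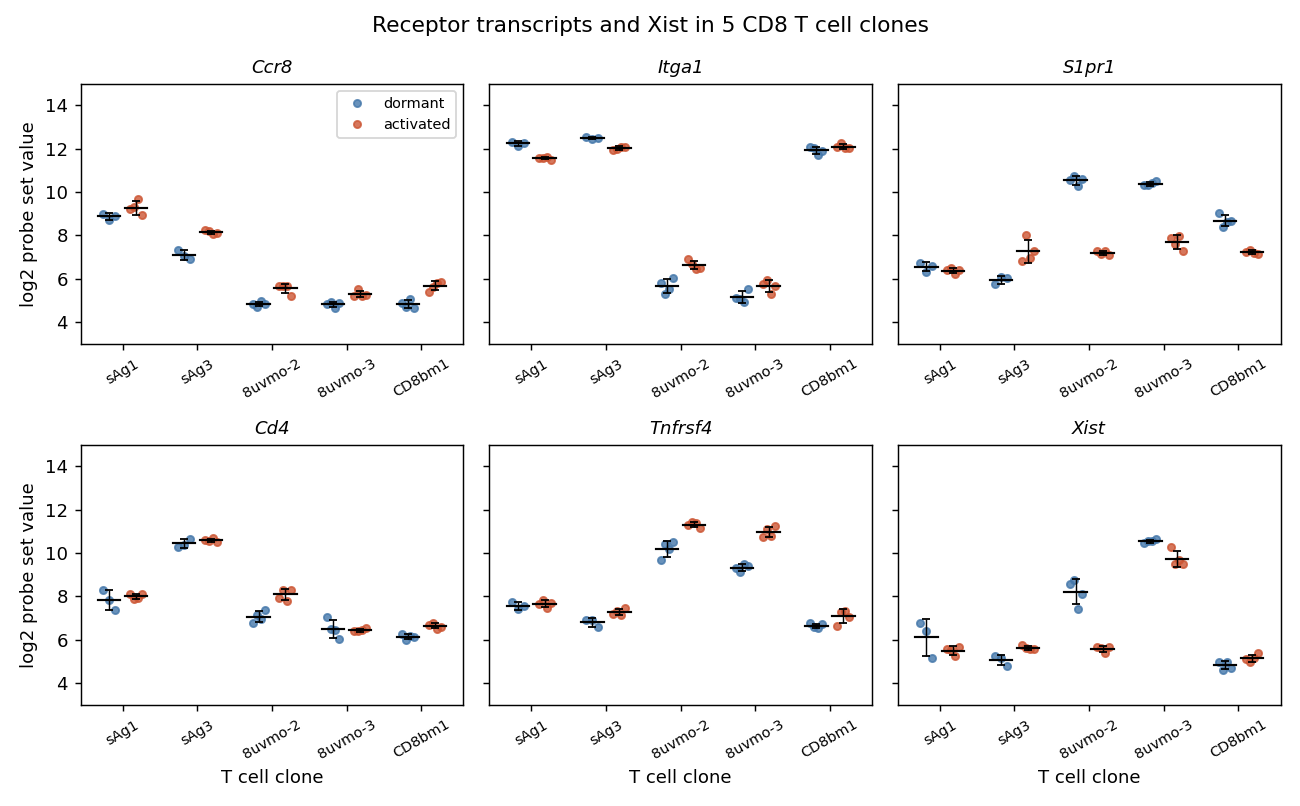
Expression (log2 value, vertical axis) of receptors and other genes by clone and state; points are arrays, black lines group means and bars 1 SD. Dormant Itga1 lay at 12.24 and 12.50 in sAg1 and sAg3, at 11.93 in CD8bm1 and at 5.67 and 5.15 in the other clones.

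After activation the same phenotypes differed in the cytokines that define them. Il5 (probe set 10376054, chromosome 11), the eosinophil growth factor, was higher on average in the IL13+ clones (4.91 ± 0.14, n = 8 and 8 arrays). Most of this came from sAg3 at 13.19 ± 0.11, since activated sAg1 stood at 7.53 ± 0.83 (arrays from 6.7 to 8.32) against 5.46 and 5.45. Il13 was at least 15.7-fold higher (3.98 ± 0.14). Activated Il13 stood at 9.51 ± 0.84 in sAg1 and 12.78 ± 0.07 in sAg3 against 7.81 ± 0.13 in 8uvmo-2 and 6.52 ± 0.11 in 8uvmo-3. Tnf was 2.54-fold lower (-1.34 ± 0.08), at 11.07 in sAg3 and 13.31 in sAg1 against 13.38 and 13.68, and Gata3, the type 2 transcription factor, was 2.15-fold higher (1.10 ± 0.052). Itga1 was at least 49.8-fold higher (5.64 ± 0.092) and Ccr8 at least 9.76-fold higher (3.29 ± 0.089). Ifng was near the array maxima on both sides, at 13.60 to 14.17 in these 4 clones, so its mean difference of -0.33 ± 0.054 can be compressed.

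The other large increases were the enamel protein gene Amelx (5.00 ± 0.13), Tm4sf19 (4.68 ± 0.096), Lncenc1 (4.52 ± 0.10) and the enkephalin precursor gene Penk (3.15 ± 0.15), the last from sAg1 at 14.23 against 8.87 in sAg3. The large decreases were Klra5 (-5.29 ± 0.15), the small GTPase gene Gem (-5.17 ± 0.15), Nrn1 (-4.92 ± 0.11), Ly6e (-4.41 ± 0.12), Sccpdh (-4.18 ± 0.16), Anxa8 (-4.12 ± 0.13), Lgi1 (-3.98 ± 0.12) and the alarmin gene Il33 (-3.76 ± 0.15). Activated CD8bm1 was low as well in Ly6e (6.32), Anxa8 (7.5), Lgi1 (4.44) and Il33 (5.48). It was higher in Klra5 (11.77), Gem (9.4), Nrn1 (12.78) and Sccpdh (8.76). Key genes with an adjusted p past the threshold but no call were Cd4 (2.03), Il10 (1.94), Eomes (1.00), Cd8b1 (0.72), Tbx21 (-0.52) and Il2 (-0.79). Prf1 (-0.20) and Cd8a (-0.09) did not pass; nor did Gzmb (-0.10), near the array maxima, and Il4 (-0.01), below 7, where a difference would hardly show.

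Genes of type 1 cytokines and their regulators were lower in 16 of 23 and higher in 2 (17 and 3 adjusted over the list alone; adjusted p = 4.49e-09, and adjusted p = 0.0169 with an estimated correlation). Ccl5 and the IL-18 receptor gene Il18r1 (-2.88 each), Xcl1 (-2.30) and Ccl4 (-1.62) are examples, of which the last 3 were low mainly in sAg3 (5.37, 9.70 and 10.25, against 10.02, 13.65 and 13.13 in sAg1). The direction of this list rested on sAg3: without that clone it turned (adjusted p = 0.913; 4.75e-14 to 0.913 over its alternatives). Type 2 genes were higher in 11 of 27 and lower in 3 (11 and 3 adjusted over the list alone; adjusted p = 0.000267, and adjusted p = 0.0288 with an estimated correlation), with Dusp4 at 2.26. Genes induced through the T cell receptor were lower in 16 of 37 and higher in 5 (17 and 5 adjusted over the list alone; adjusted p = 0.000136, and adjusted p = 0.0454 with an estimated correlation). Tnfrsf4 (-3.67), which encodes the costimulator OX40, Fosl1 (-2.18), Nr4a2 (-1.71) and Egr1 (-1.65) are examples; without sAg3 the direction of this list turned too (adjusted p = 0.97; 1.49e-07 to 0.97 over its alternatives). Of 20 chemokine ligands, 9 were lower and 3 higher (9 and 4 adjusted over the list alone); the list passed as lower (adjusted p = 0.0198, adjusted p = 0.354 with an estimated correlation) although its median was 0.06 (mean -0.57), and without sAg3 its direction turned (adjusted p = 0.913; 0.00299 to 0.913 over its alternatives). Ribosome biogenesis genes were lower in 24 of 41 and higher in 0 (30 and 0 adjusted over the list alone; adjusted p = 5.14e-10, adjusted p = 0.402 with an estimated correlation). Of 47 cell cycle genes, 0 were higher and 0 lower (0 and 0 adjusted over the list alone; adjusted p = 0.841).

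Of the 29 lists 8 passed, and 3 of them with the estimated correlation too. After activation 409 probe sets were called, 156 higher and 253 lower in the IL13+ clones. With clone means as replicates 6 remained (1 higher, 5 lower), with Itga1 among them but not Il13 or Il5. The count was 1175 without sAg1, 752 without 8uvmo-2 and 619 without the condition on the clones, and 120 probe sets passed in every pair of clones.

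**Figure D3:**
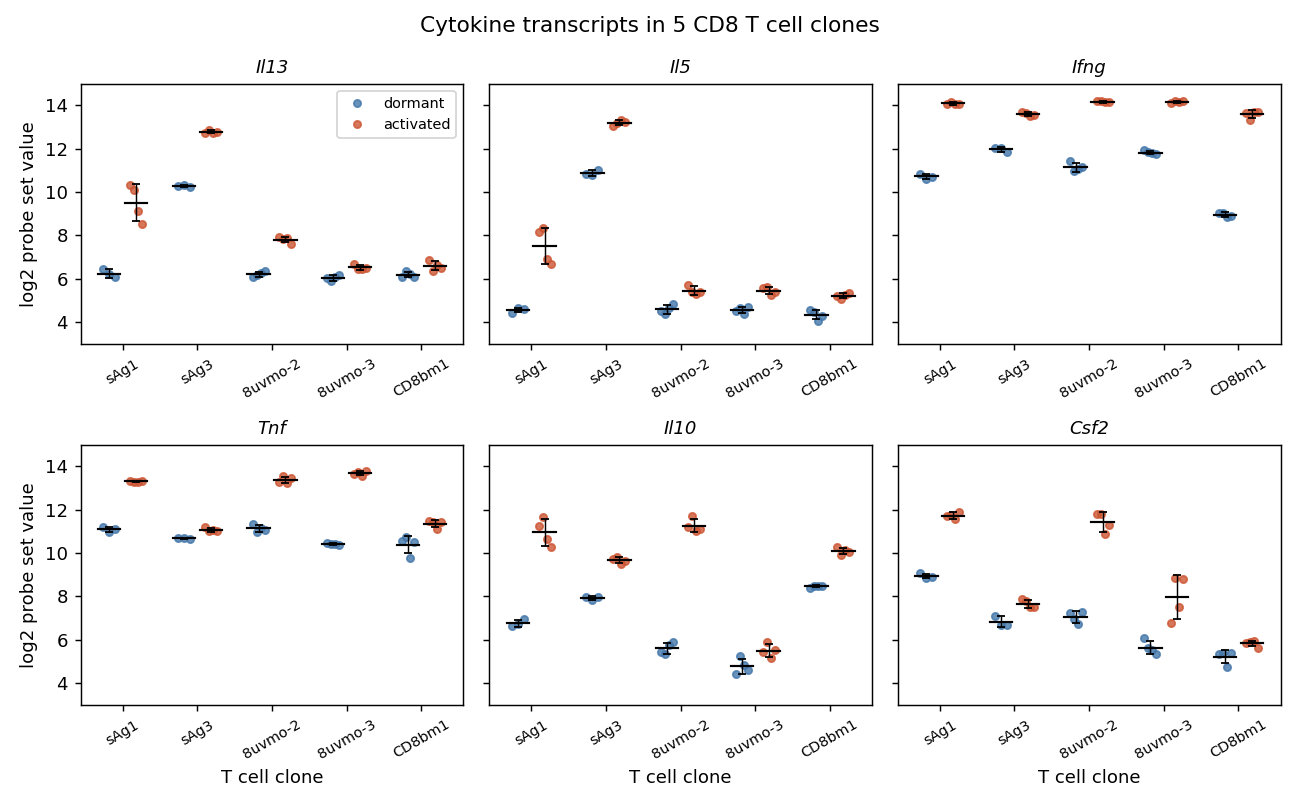
Expression (log2 value, vertical axis) of 6 cytokines by clone and state; points are arrays, black lines group means and bars 1 SD. Activated Il13 means were 9.51 in sAg1 and 12.78 in sAg3, and 7.81, 6.52 and 6.60 in 8uvmo-2, 8uvmo-3 and CD8bm1.

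Against the alloreactive clone CD8bm1, the dormant IL13+ clones differed in receptor, cytokine and metabolic genes. Ccr8 was at least 8.92-fold higher (3.16 ± 0.12, n = 6 and 4 arrays) and Ifng 5.24-fold higher (2.39 ± 0.07), each in both IL13+ clones. The mean differences of Il13 (2.07 ± 0.18) and Il5 (3.38 ± 0.19) came from sAg3, since dormant sAg1 lay at 6.24 and 4.56 beside 6.19 and 4.34 in CD8bm1. B4galnt2, a glycosyltransferase gene, was at least 95.6-fold higher (6.58 ± 0.097). Klra5, an NK receptor gene, was at least 185-fold lower (-7.53 ± 0.19), and Me1, the malic enzyme gene, at least 89.1-fold lower (-6.48 ± 0.13). Further increases were Clgn (6.08 ± 0.11), the chaperone gene Dnajb9 (5.86 ± 0.15), Ms4a4b (5.39 ± 0.17), Lilr4b (5.06 ± 0.18), Acpp (4.91 ± 0.12), Gmfg (4.80 ± 0.063) and the decoy receptor gene Tnfrsf11b (4.58 ± 0.22). Further decreases were the glycolytic gene Aldoc (-6.52 ± 0.29), Adgrg7 (-6.16 ± 0.10), Itm2a (-6.14 ± 0.10), Nrn1 (-5.98 ± 0.14), the hypoxia-induced carbonic anhydrase gene Car9 (-5.86 ± 0.15) and Mdga2 (-5.72 ± 0.093).

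Cd4 (3.00 ± 0.15), Eomes (2.04 ± 0.15) and Gata3 (1.12 ± 0.068) were higher and Il10 lower (-1.11 ± 0.18) than in dormant CD8bm1; Eomes was at 9.24 in sAg3 and at 5.43 in sAg1, beside 5.29 in CD8bm1. Tnf (0.49), Cd8b1 (-0.27) and Gzmb (-0.39) passed the adjusted p but not the minimum difference. Cd8a (0.14), Prf1 (0.12), Il4 (0.09), Tbx21 (0.02) and Il2 (0.01) did not pass. Cholesterol synthesis genes were lower in 17 of 20 and higher in 1 (17 and 2 adjusted over the list alone; adjusted p = 2.77e-11, adjusted p = 0.0885 with an estimated correlation), with Dhcr7 at -2.66 and Cyp51 at -2.05. Cell cycle genes were lower in 41 of 47 and higher in 1 (43 and 1 adjusted over the list alone; adjusted p = 7.17e-10, adjusted p = 0.412 with an estimated correlation), with the mitotic kinase gene Bub1 at -3.64. Glycolysis genes were lower in 16 of 17 and higher in 0 (16 and 1 adjusted over the list alone; adjusted p = 6.59e-07, adjusted p = 0.255 with an estimated correlation), and hypoxia genes were lower in 15 of 19 (15 adjusted over the list alone; adjusted p = 8.34e-05, adjusted p = 0.408 with an estimated correlation). Type 1 genes were higher in 13 of 23 and lower in 3 (13 and 3 adjusted over the list alone; adjusted p = 0.000297, adjusted p = 0.0908 with an estimated correlation), and type 2 genes in 10 of 27 with 1 lower (10 and 1 adjusted over the list alone; adjusted p = 0.00177, adjusted p = 0.0885 with an estimated correlation). Of the 9.17-fold difference in lymphotoxin beta (Ltb) and the difference of 3.71 in Il18r1, sAg1 carried most, at 12.79 and 11.88 against 9.50 and 4.92 in sAg3. The interferon regulator Irf1 was 8.43-fold higher (3.08 ± 0.15) and the IL13+ clones had at least 4.89-fold more Zbtb7b, which encodes the CD4 lineage factor ThPOK.

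After activation the IL13+ clones exceeded CD8bm1 in several cytokines. Il5 was at least 35.3-fold higher (5.14 ± 0.18, n = 8 and 4 arrays), Il3 at least 27.1-fold (4.76 ± 0.16), Il13 at least 23.4-fold (4.55 ± 0.17) and Csf2, a myeloid growth factor, at least 14.5-fold (3.86 ± 0.24). Il3 and Csf2 were both at 11.73 in sAg1, and at 7.84 and 7.66 in sAg3. For Il5 sAg3 carried most of the difference, at 13.19 against 7.53 ± 0.83 in sAg1 and 5.22 in CD8bm1. The chemokine genes Xcl1 (3.71 ± 0.13) and Ccl9 (2.35 ± 0.16) were higher too. Klra5 was at least 256-fold lower (-8.00 ± 0.18) and Nrn1 at least 94.4-fold lower (-6.56 ± 0.13). B4galnt2 (5.59 ± 0.092), Amelx (5.35 ± 0.16), Clgn (5.34 ± 0.10), Dnajb9 (5.28 ± 0.14), Ly6a2 (5.02 ± 0.16) and Gmfg (4.77 ± 0.06) were the other large increases. Car5b (-5.80 ± 0.11), Me1 (-5.35 ± 0.12), Adgrg7 (-5.22 ± 0.095), Sema3d (-5.00 ± 0.11), Rny1 (-4.93 ± 0.34) and Enpp6 (-4.91 ± 0.13) were the other large decreases. Of the key genes, Cd4 (2.65), Il2 (1.59), Eomes (1.46) and Gata3 (1.05) were called higher, Eomes from sAg3 (8.47, against 5.73 in sAg1 and 5.64 in CD8bm1). Tnf (0.83), Cd8a (0.65) and Ifng (0.25) passed the adjusted p only, and Il10 (0.23), Tbx21 (0.09), Gzmb (0.05), Il4 (-0.01), Cd8b1 (-0.08) and Prf1 (-0.13) did not pass, where Gzmb was near the array maxima and Il4 below 7.

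Interleukins and growth factors were higher in 21 of 33 and lower in 1 (21 and 1 adjusted over the list alone; adjusted p = 1.81e-11, and adjusted p = 6.29e-05 with an estimated correlation). Type 2 genes were higher in 15 of 27 and lower in 0 (17 and 0 adjusted over the list alone; adjusted p = 4.23e-09, and adjusted p = 0.000226 with an estimated correlation). Type 1 genes were higher in 15 of 23 and lower in 4 (15 and 4 adjusted over the list alone; adjusted p = 7.79e-08, and adjusted p = 0.0133 with an estimated correlation). Genes induced through the T cell receptor were higher in 17 of 37 and lower in 4 (19 and 4 adjusted over the list alone; adjusted p = 0.000204, and adjusted p = 0.039 with an estimated correlation), with Nr4a1 at 2.48, Tnfrsf18 at 2.22 and RANK ligand (Tnfsf11) at 2.13. The inhibitory receptor gene Ctla4 went the other way, at -3.47 ± 0.37. Of 20 chemokine ligands, 11 were higher and 0 lower (12 and 0 adjusted over the list alone; adjusted p = 1.25e-05, and adjusted p = 0.0384 with an estimated correlation).

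Against CD8bm1, 13 of the 29 lists passed in each state, of which 0 in the dormant and 5 in the activated state also passed with the estimated correlation. Dormant, 1699 probe sets were called against CD8bm1 (735 higher, 964 lower), and activated, 858 (472 higher, 386 lower). The alloreactive side is 1 clone, so its clone and its phenotype cannot be told apart. With clone means as replicates the counts were 168 and 61, and none of the 15 key genes was among them.

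Genes that set both IL13+ clones apart from all 3 other clones were those called the same way in both comparisons of a state. In the dormant state 93 probe sets were higher, among them Tmem273, Ccr8 and Amelx. Hpgds was also called, but lay at 9.44 in sAg3 beside 8.65 in 8uvmo-2. Prl2c5, a prolactin family gene, was called too, but lay at 8.33 in sAg1 and below 7 in sAg3 (4.68). Another 229 were lower, among them S1pr1, Lxn, Ndnf, Tmem159 and Mr1, the antigen-presenting molecule of MAIT cells. Mr1 stood at 6.41 and 5.54 in sAg1 and sAg3 and at 9.91 to 10.20 in the other dormant clones. After activation 49 were higher, among them Il5, Il13, Ccr8, Amelx, Tm4sf19 and Arntl, and 56 were lower, among them Gem, Nrn1 and Lxn. Klra5 and the glucose transporter gene Slc2a3 were called lower too. Klra5 was below 7 in 8uvmo-2 as well (5.99), and Slc2a3 was at 10.6 in sAg3 beside 11.21 in CD8bm1. Independent lists would share 7.5, 22.4, 3.15 and 4.17 probe sets. Because both comparisons share the IL13+ arrays, the overlap was also taken with a different IL13+ clone on each side: it was 70 and 66 for dormant increases (13 and 34 for independent lists), 244 and 177 for dormant decreases (32.7 and 52.5), 50 and 52 for activated increases (6.4 and 15.6) and 66 and 58 for activated decreases (7.22 and 15). Sharing of this size was not particular to the IL13+ clones: in a fit of any 2 of the 5 clones against the other 3, 179 to 884 probe sets were called and separated in the dormant state and 139 to 598 in the activated state, with sAg1 and sAg3 at 484 and 190 (a comparison chosen after the values were seen). With clone means as replicates 8 and 1 probe sets remained in the dormant and activated states, and with a call required in every pair of clones 65 and 38. The dormant count was 610 without sAg1 and 670 without sAg3, the activated count 481, 232 and 169 without sAg1, sAg3 and 8uvmo-2.

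The effect of activation itself differed between the phenotypes; the difference is given as the effect in the IL13+ clones minus that in the IL13-negative clones, and effects in single clones are relative to the array medians. S1pr1 fell by 3.74 in 8uvmo-2 and by 3.09 in 8uvmo-3, against -0.58 in sAg1 and 0.90 in sAg3 (difference 3.59 ± 0.17). The effect on Il13 was 2.86 in sAg1 and 2.07 in sAg3, against 0.09 in 8uvmo-3 (difference 1.84 ± 0.21); 8uvmo-2 went from 6.22 dormant to 7.81 activated on the deposited values. The difference for Il5 was 1.76 ± 0.21. The difference for Tnf (-1.45 ± 0.12) went with an effect of -0.01 in sAg3, against 1.85 in 8uvmo-2 and 2.87 in 8uvmo-3. On the deposited values Tnf went from 10.67 to 11.07 in sAg3. Probe sets with a mean of 10 to 11 had a median state shift of 0, so centring lowers this effect. On the deposited values sAg1 went from 11.10 dormant to 13.31 activated, close to 8uvmo-2 (11.13 to 13.38). Crtam, an adhesion molecule of activated T cells (-3.58 ± 0.13), Il33 (-3.57 ± 0.23), Nrn1 (-3.33 ± 0.15), the chemokine gene Ccl9 (-2.77 ± 0.19), the nuclear receptor gene Nr4a2 (-2.76 ± 0.15), Lta (-2.51 ± 0.14), Akr1b8 (-2.48 ± 0.11) and Gem (-2.46 ± 0.22) also had negative differences. On the deposited values Crtam, Nr4a2 and Lta changed by 2.6, 1.72 and 2.42 in sAg1 but by -0.82, -0.16 and 0.12 in sAg3. Crtam rose by 3.06 in 8uvmo-3, close to sAg1. Akr1b8 rose by 4.61 in 8uvmo-2 and by 1.7 in 8uvmo-3. Ripor2 (2.90 ± 0.13), the integrin gene Itgam (2.78 ± 0.30), Ccdc38 (2.64 ± 0.14), Cpa6 (2.61 ± 0.10), Prss12 (2.60 ± 0.19), Aldoc (2.58 ± 0.33) and Cd7 (2.55 ± 0.42) had positive differences. Dormant 8uvmo-2 arrays spread widely in Cd7 (SD 1.66), Itgam (SD 0.98) and Aldoc (SD 0.93). On the deposited values Itgam changed by -4.03 in 8uvmo-2 but by -1.39 in 8uvmo-3. Of the genes with positive differences, S1pr1, Itgam, Ccdc38, Cpa6, Aldoc and Cd7 lay below 7 in both dormant IL13+ clones, and Ripor2 and Prss12 in sAg1, so a fall there had little room to show. Ccdc38, for example, fell by 2.91 in 8uvmo-2 and by 2.83 in 8uvmo-3, and was at 4.65 and 4.74 in dormant sAg1 and sAg3. Of the other key genes, Eomes was called (-1.01 ± 0.17; -0.72 after quantile normalization), Gzmb (-0.26), Prf1 (-0.57) and Il2 (-0.89) passed the adjusted p only, and Gata3 (0.20), Cd8a (0.17), Cd8b1 (0.08), Tbx21 (0.00), Il4 (-0.15), Ifng (-0.19), Il10 (-0.21) and Cd4 (-0.32) did not pass.

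Genes induced through the T cell receptor had a negative difference in 23 of 37 and a positive one in 2 (23 and 4 adjusted over the list alone; adjusted p = 1.73e-11, and adjusted p = 0.000831 with an estimated correlation), with Fosl1 at -2.18 and Myc at -1.35. Without sAg3 this list turned its direction (adjusted p = 0.789; 1.01e-22 to 0.789 over its alternatives). Unfolded protein response genes had a negative difference in 19 of 21 and a positive one in 1 (20 and 1 adjusted over the list alone; adjusted p = 2.42e-22, and adjusted p = 0.00207 with an estimated correlation), with Herpud1 at -1.09. Amino acid transport and one-carbon genes had a negative difference in 16 of 26 and a positive one in 1 (18 and 2 adjusted over the list alone; adjusted p = 3.09e-10, and adjusted p = 0.0453 with an estimated correlation), with Slc7a5 and Slc1a4 at -1.84 and asparagine synthetase (Asns) at -1.29. Chemokine and homing receptors had a positive difference in 9 of 28 and a negative one in 2 (10 and 2 adjusted over the list alone; adjusted p = 1.71e-05, and adjusted p = 0.00207 with an estimated correlation), with Gpr15 at 2.04 (5.67 in dormant sAg1) and Gpr183, a receptor for oxysterols, at 1.61 (6.51 in dormant sAg3). Cell cycle genes had a positive difference in 24 of 47 and a negative one in 1 (29 and 1 adjusted over the list alone; adjusted p = 2.06e-08, adjusted p = 0.568 with an estimated correlation), with the cyclin gene Ccnb2 at 2.41 ± 0.44. Relative to all probe sets, this list fell with activation in all clones but sAg1. In sAg3 the list medians of single arrays overlapped between the states (7.92 to 8.77 dormant, 7.76 to 8.3 activated). The fall in 8uvmo-2 came mostly from dormant replicates 1 and 3. The list medians of dormant replicates 2 and 4 (8.41 and 8.04) lay within the range of its activated arrays (7.67 to 8.58). Without sAg1 this list did not pass (adjusted p = 0.161; 1.38e-14 to 0.568 over its alternatives), and without 8uvmo-2 6 had a positive and 1 a negative difference. Of the 29 lists 12 passed, 4 of them also with the estimated correlation. In total 456 probe sets were called, 326 with a positive and 130 with a negative difference. With clone means as replicates limma called 0, with 1091 at an unadjusted p under 0.05 and a lowest adjusted p of 0.0924; the count was 879 without sAg1, 738 without sAg3 and 791 without 8uvmo-3.

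Clones of 1 phenotype also differed from each other. Dormant sAg1 and sAg3 differed at 1764 probe sets (876 higher and 888 lower in sAg1), and activated at 1177 (609 and 568). Clones 8uvmo-2 and 8uvmo-3 differed at 1073 (592 higher and 481 lower in 8uvmo-2) and 725 (390 and 335). Il5 was 6.32 lower in dormant sAg1 than in sAg3 and 5.66 lower after activation; Il13 was 4.05 and 3.26 lower, and Eomes 3.81 and 2.74 lower. Activated sAg1 had more Tnf (2.24) and more type 1 transcripts than sAg3, with 20 of 23 genes higher and 3 lower (20 and 3 adjusted over the list alone; adjusted p = 3.22e-15, and adjusted p = 0.000595 with an estimated correlation). Activated 8uvmo-2 had 5.76 more Il10 than 8uvmo-3, at 11.26 against 5.50.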

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

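Of the tests in this part, the regroupings of the clones, also those of 2 of the 5, the tests of an array offset, of induction, of chance over genes, of hybridisations, of whole feeder spleen and of expression by the clone itself were chosen only after the result was seen. The regroupings of arrays, the sections of chromosomes and the second macrophage list were set before their results were seen.

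The effect of activation differed between the IL13+ and IL13-negative clones, by the test of the difference itself, at 456 probe sets. That test rests on the spread between arrays: with clone means as replicates the lowest adjusted p (limma) was 0.0924. Among the key and plotted genes those called were S1pr1 (3.59), Il13 (1.84), Il5 (1.76) and Xist (1.71) with a positive difference (IL13+ minus IL13-negative), and Tnf (-1.45), Itga1 (-1.32), Tnfrsf4 (-1.08) and Eomes (-1.01) with a negative one. S1pr1 and Xist lay below 7 on average in both dormant IL13+ clones, so a fall there had little room to show; Xist still went from 6.11 to 5.5 in sAg1. Itga1, Eomes and Il5 lay below 7 in both IL13-negative clones in both states, where values carry the shift of dim probe sets described below. After quantile normalization the differences of Itga1 and Eomes were -0.75 and -0.72, under the minimum of 1. Tnfrsf4 and Xist were chosen after their values were seen. Xist, the X-inactivation transcript, stood at 8.22 in dormant and 5.58 in activated 8uvmo-2, and at 10.55 and 9.73 in 8uvmo-3.

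Single arrays were regrouped within a state, in a fit with 1 mean per phenotype and no condition on clones, so its counts differ from the 1077, 619, 1821 and 938 called with 1 mean per clone. Regrouping arrays breaks up the clones, so it tests chance over arrays and leaves open whether other groupings of whole clones would give as many. Chance over arrays could be excluded for the phenotype counts: 1055 against a highest other of 729 for IL13+ against IL13-negative clones dormant, 589 against 413 activated, 1794 against 1458 for IL13+ clones against CD8bm1 dormant and 907 against 436 activated. The same held for the probe sets apart from both sides dormant (410 against 104); activated, 2 of 100 groupings, the real one included, gave 168 or more, and the highest other gave 235. For the difference in activation this fit called 247, not the 556 called with 1 mean per clone, 4 of 100 groupings gave as many, and the highest other, 1259, was several times larger, which points to a structure of the samples. Within clones, where regrouping breaks up no clone, chance over arrays could be excluded for activation over all clones (1554 against 14). The same held within each clone: 2538 against 1144 in sAg1, 1177 against 352 in sAg3 and 2779 against 620 in 8uvmo-2. In 8uvmo-3 the counts were 2358 against 442, and in CD8bm1 1696 against 291. Chance over arrays could also be excluded for activated sAg1 against sAg3 (1178 against 38). So it could for 8uvmo-2 against 8uvmo-3 dormant (1075 against 263) and activated (725 against 141). Arrays of 1 group may come from 1 culture, in which case the real grouping is bound to give the most. Chance between cultures was therefore not tested. Elsewhere 1 grouping, the real one, gave as many. For dormant sAg1 against sAg3 the 10 regroupings were too few for a share under 0.05 (1763 against 0). Regrouping whole clones of both phenotypes allows 3 pairings, too few for a share under 0.05: the counts were 784 against a highest other of 611 dormant, 409 against 401 activated, and 456 against 317 for the difference in activation. For any 2 of the 5 clones against the other 3, the separated counts of other pairs exceeded those of sAg1 with sAg3 (484 dormant, 190 activated) for 4 pairs in each state.

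In groups of 4 arrays, 176 values were tested, of 21 genes and the array median in each of 8 groups. In 9 of them, all of single genes, 1 array lay far from the rest, where chance gives about 1 in 20. The gap as a share of the range was 0.842 for Gata3 in dormant CD8bm1 (9.29 against 8.91 to 8.97), 0.924 for Csf2 in dormant CD8bm1 (4.75 against 5.36 to 5.41) and 0.909 for Gata3 in activated sAg1 (9.53 against 9.73 to 9.75). It was 0.88 for Cd8a in activated sAg1, 0.885 for Gata3 and 0.857 for Gzmb in activated sAg3, 0.978 for Ccr8 in activated 8uvmo-2, and 0.917 for Ifng and 0.861 for Tnf in activated CD8bm1. Leaving out any 1 array moved no count of called probe sets by more than 1.5 times.

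Probe sets without a gene name in the annotation were not used in the comparisons. Of these 12146, 654 were called for activation (469 higher, 185 lower) and 1132 between dormant sAg1 and dormant sAg3 (1006 higher and 126 lower in sAg1).

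Dim probe sets (mean below 7, 12100 of them) were higher on the activated arrays by a median of 0.515, while bright ones (mean above 9, 5620) differed by -0.0452. Induction by the stimulus was argued against, since the lowest over highest shift across clones was 0.94 for dim probe sets and 0.33 for genes induced through the T cell receptor. An offset of the arrays at low signal is a candidate explanation. Markers of B, erythroid, stromal and epithelial cells were higher by a median of at least 0.59 in each clone. Markers at low signal are themselves dim probe sets, so their rise restates the pattern and does not decide its cause. State and array set go together here, so an array offset and a general effect of stimulation on RNA cannot be separated further. Small increases of dim genes after activation, including the stromal and erythroid lists, carry this shift, whatever its cause.

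Genes of whole chromosomes lay higher or lower together in a clone, set against the median of the other clones, in 23 of 100 pairs of clone and chromosome in both states (limits of 0.1 on the median shift and 8 on the mean, set after the values were seen). The largest was chromosome 8 in sAg3, at 0.38 dormant and 0.34 activated over 399 genes, with the next largest dormant in chromosome 17 of 8uvmo-2 (0.31 dormant, 0.22 activated) and the next largest activated in chromosome 12 of sAg3 (0.28 dormant, 0.32 activated). Chance over genes was argued against (0 of 1000 shuffles gave as many). So were differences between hybridisations, since the 27 pairs found dormant had a median shift of 0.155 in their own direction on the activated arrays. Of 92 sections (4 per chromosome) of the 23 pairs, 93.5% carried the shift. These pairs were chosen by their median over the whole chromosome, which makes shifted sections likely beforehand. The sections thus give no separate support against a few clusters of neighbours. Gain or loss of chromosome copies in part of the cells of a cultured clone may explain the shifts, as a hypothesis: 1 extra copy beside 2 in all cells would give 0.585, and no DNA was measured. Each clone also enters the reference of the others, so pairs on 1 chromosome are not independent. On chromosomes 1, 12 and 17 both IL13+ clones shifted together, opposite to 8uvmo-2. Dormant chromosome 12 was at 0.23 in sAg1 and 0.28 in sAg3, against -0.27 in 8uvmo-2 and -0.06 in 8uvmo-3. Differences between clones on the shifted chromosomes may carry shifts of this size, or more where shifts are opposite. A shift of 0.38 alone is below the log2 difference of 1 needed for a call.

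Some transcripts of macrophages were raised in dormant sAg1 over the mean of the other 4 dormant clones: Lyz2, the macrophage lysozyme, at 9.26 against 5.40, Mmp12 at 7.98 against 5.09, Cybb at 6.95 against 4.97 and Gpnmb at 6.77 against 4.82 (genes chosen after their values were seen). Of the 26 measured markers of macrophages and dendritic cells, 11 were higher, 4 of them by 1 or more, and 4 were lower (Itgax by 1.96, Cd68 by 0.88, Hmox1 by 0.72 and Itgam by 0.67), with a median of 0.124. A second list of abundant macrophage genes lay at percentile 100 of 10000 random lists (median 0.203, 12 of 22 higher and 1 lower), of which 5 members were above 8 in the other clones too, but C1qa, C1qb, C1qc, Cd14, Csf1r and Apoe, a group picked after seeing the values, had a median of 0.175, so RNA carried over from macrophages may be a source and stays open. Whole feeder spleen, B cells included, was argued against by B and plasma cell markers at a median of -0.04 (13 measured), with Ighm at 0.03 and Cd79b at -0.08 from low levels, as Lyz2 was. In all, 3 of them were higher past the test, Cd79a by 0.32, Fcrla by 0.28 and Ebf1 by 1.73, the last also in activated sAg1 (1.67). Feeder spleen without its B cells would escape this test and cannot be told apart from carried-over macrophages. Expression by the clone itself stays open, since the raised members were 0.24 higher by median in activated sAg1 in the first list (4 genes), 0.61 in the second (4 genes, with Mmp12 at 1.06) and 0.34 over both. The labels used here give no sort or gate, and dormant differences of sAg1 in such genes are subject to both.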

How the results depend on the processing

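Of the alternatives below, all rows of the file, counts with a clone left out, a call in every pair of clones and lists after quantile normalization were chosen only after the result was seen. Arrays have no depth. Probe sets treated as near background (means below 7) limit what low genes can show. A log2 of the value plus 1, or a pseudocount of 16, had been intended and was not run, since the values were log2 already. Results are given in the order activation, IL13+ against IL13-negative dormant and activated, IL13+ against CD8bm1 dormant and activated, apart from both dormant and activated, and difference in activation; then sAg1 against sAg3 dormant and activated, 8uvmo-2 against 8uvmo-3 dormant and activated, and activation within sAg1, sAg3, 8uvmo-2, 8uvmo-3 and CD8bm1. Counts within 1.5 times the reported one were found for 17 of 19 alternatives for activation, 13 and 12 of 19 for IL13+ against IL13-negative, 13 of 17 in both states against CD8bm1, 12 and 11 of 19 apart from both, and 12 of 18 for the difference in activation.

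With no minimum on the log2 difference, which only loosens the call, the counts were 16537, 4860, 3779, 8434, 5954, 2274, 1401 and 3071; then 8166, 8284, 7339 and 6116, and 18638, 17101, 19321, 19072 and 18585. With treat against a difference of 1, a stricter test, they were 809, 428, 241, 925, 492, 120, 58 and 97; then 928, 674, 542 and 345, and 949, 168, 1188, 933 and 371. Without the condition on the clones, 619 were called between the activated phenotypes and 192 apart from both activated. With clone means as replicates, where fewer samples enter, the counts were 36 and 6, 168 and 61, 8 and 1, and 0 for the difference in activation (limma; 1091 at an unadjusted p under 0.05). With the clone as a random block 202 were apart from both dormant. In every pair of clones on its own, 212 and 120, 984 and 464, and 65 and 38 passed.

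Activation within sAg3 gave 627 without dim probe sets and 624 after quantile normalization; the cause was not tested. All rows of the file, which tests more, gave 2888 for dormant sAg1 against sAg3 and 4375 and 1867 for activation within sAg1 and sAg3. Without sAg1, IL13+ against IL13-negative gave 1540 and 1175, apart from both 610 and 481, and the difference in activation 879. Without sAg3, apart from both gave 670 and 232 and the difference in activation 738. Without 8uvmo-2, IL13+ against IL13-negative gave 1231 and 752 and apart from both activated 169; without 8uvmo-3 the difference in activation gave 791. The condition on the clones is easier to meet with fewer clones. With all clones and no condition, however, IL13+ against IL13-negative gave 1077 and 619, apart from both 426 and 192, and the difference in activation 556. An easier condition thus cannot account for the whole rise without sAg1, and no other cause was tested.

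Leaving out 1 array gave 1420 to 1468 for activation, 744 to 831 and 402 to 418 for IL13+ against IL13-negative, 1625 to 1798 and 855 to 872 against CD8bm1, 283 to 359 and 102 to 112 apart from both and 416 to 496 for the difference in activation. It gave 1718 to 1796 and 1162 to 1215 for sAg1 against sAg3, 1053 to 1177 and 701 to 763 for 8uvmo-2 against 8uvmo-3, and 2525 to 2635, 1137 to 1262, 2703 to 2881, 2222 to 2522 and 1574 to 1808 for activation within the clones.

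Of 511 results of named genes, 507 kept their direction and their side of the adjusted p threshold alone after centring and 509 after quantile normalization; with clone means 140 did and 371 were no longer past it. The minimum difference and the condition on clones are not part of these counts: Il13, Tnf and Prf1 in activation lost their calls after centring. Activation reversed after centring for Tbx21 (-0.14), Eomes (-0.12), Cd8b1 (-0.14) and Cd4 (-0.05), and after quantile normalization for Eomes (-0.15), since the array medians differ by state. Of 174 list results, 120 kept their side with an estimated correlation and 54 did not. Lists that reversed without sAg3, given by adjusted p, were type 1 dormant (0.921), type 1 (0.913), genes induced through the T cell receptor (0.97) and chemokine ligands (0.913) between the activated phenotypes, and type 1 (0.912), cytotoxic (0.664) and T cell receptor-induced genes (0.789) in the difference in activation. Without sAg1 the unfolded protein response between the activated phenotypes (0.927), amino acid genes against dormant CD8bm1 (0.944) and the unfolded protein response against activated CD8bm1 (0.874) reversed, and without 8uvmo-3 cytotoxic genes in the difference in activation (0.908). The cause was not tested. Over all alternatives these adjusted p-values ran from 1.01e-22 to 0.97.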

Other observations

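All comparisons in this part were chosen only after the result was seen. Grouping 2 of the 5 clones against the other 3 gave most separated probe sets for sAg3 with CD8bm1, at 884 dormant and 598 activated. For sAg1 with sAg3 the counts were 484 and 190, which 3 other pairs also exceeded in each state: dormant sAg1 with 8uvmo-3 (627), 8uvmo-2 with CD8bm1 (504) and 8uvmo-2 with 8uvmo-3 (495), and activated 8uvmo-2 with 8uvmo-3 (333), sAg1 with 8uvmo-3 (331) and sAg1 with 8uvmo-2 (199). Dormant sAg3 and CD8bm1 shared low Il18r1 (4.92 and 4.69, against 11.52 to 12.35 in the other clones), low Cxcr6 (5.55 and 5.26, against 8.28 to 12.75), low Csf1 (5.84 and 5.69, against 9.89 to 11.09) and high Itgb1 (12.61 and 12.50, against 6.94 to 7.55).

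Among probe sets lower in both IL13+ clones in every pair of clones, 3 genes were picked after their values were seen. Dormant Phyh, which starts the breakdown of branched fatty acids, was at 5.42 in sAg1 and 5.13 in sAg3 against 9.04 to 9.59 in the other clones, the mitochondrial oxidation gene Hadh at 6.04 and 5.83 against 8.51 to 11.21, and the fatty acid transporter gene Slc27a6 at 6.09 and 5.73 against 9.08 to 10.53. No list of fatty acid genes was tested, so these values say nothing about a pathway.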
